A study of Mus musculus with 4 samples.

How the data were processed

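Cells of the mouse colon were profiled by droplet single-cell RNA sequencing with a 3' kit and antibody hashtags, in 2 batches. Per the labels' protocols, 4 conditions were tagged with 1 hashtag antibody each: untreated wild type, untreated JUP-KO, wild type given dextran sulfate sodium (DSS, a chemical that injures the colon lining) and JUP-KO given DSS. The tagged cells of a batch were then mixed, sorted for viability and loaded together. The labels state 23000 to 25000 cells loaded and about 14000 targeted per batch. Each batch has 1 gene expression library and 1 hashtag library. The processed files of both are kept with the gene expression library. Whether the batches are separate mice is not given in the sources used here. P-values therefore measure the spread between these samples, which may be partly technical.

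The deposited values are raw UMI counts of 32285 genes and 4 antibody features over all barcodes of a batch, 2082989 in batch 1 and 1567140 in batch 2. Per the submitters' processing notes the authors used Cell Ranger 7.0.0 and the mm10 build. The annotation release is not given in the sources used here. Of the gene identifiers, 32158 (99.6%) were found in GENCODE M21, of the same build, and 31436 had the same symbol there. Coordinates come from that annotation, counted from 1.

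The antibody features carry the names Ctrl_WT, Ctrl_DSS, TG_WT and TG_DSS, and nothing in the sources used here links a name to an antibody number. Read by name, TG_WT would be untreated JUP-KO and Ctrl_DSS would be wild type given DSS. Read in the order of the antibody numbers in the protocol, these would change places, while Ctrl_WT and TG_DSS stay untreated wild type and JUP-KO given DSS. Conditions had been assigned by antibody number before the data were examined. The reading by name was taken up on opening the files, before Jup or the neutrophils were looked at. Reporting by tag name, without choosing a reading, was decided after both had been seen. All comparisons are therefore between cells labelled with tag names.

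Cells were called in 2 steps. Barcodes at or above 0.1 of the 99th percentile of UMIs among the 14000 richest were cells. Barcodes below it with at least 500 UMIs were cells when their profile departed from the ambient one, which was taken from barcodes with at most 100 UMIs (10000 simulated draws, adjusted p at most 0.01). This gave 9993 cells in batch 1 and 9357 in batch 2. Cells were kept with at least 250 genes and at most 25% mitochondrial UMIs. The mitochondrial limit removed 2823 and 2853 cells, and the gene limit applied to 216 and 1134. This left 7157 and 6472 cells, 13629 in all. Called cells held 88.8% and 90.9% of all UMIs.

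Tags were called per batch and tag with a 2-component Gaussian mixture on log10 counts, and a cell over exactly 1 threshold was kept. Cells over more than 1 threshold were left out as doublets (266 or 3.72% in batch 1, 699 or 10.8% in batch 2). Cells over none were left out of comparisons as untagged (4541 or 63.4%, and 2612 or 40.4%). The 5511 cells kept were, in batches 1 and 2, 177 and 92 labelled Ctrl_WT, 407 and 492 labelled Ctrl_DSS, 521 and 1263 labelled TG_WT, and 1245 and 1314 labelled TG_DSS. An alternative highest-tag rule asked that the highest tag, relative to its batch median, be at least 3 times the next. It gave the same call to 87 and 68 of these Ctrl_WT cells and 180 and 232 of Ctrl_DSS. For TG_WT these were 437 and 1247, and for TG_DSS 600 and 1086. The others kept no call by that rule. No other doublet caller entered the main results. Scrublet was run as an alternative and called 9.00% in batch 1. In batch 2 its automatic threshold called 0% and had not worked, so the top 8.39% by score were taken instead.

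Cells of both batches were clustered together with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden at resolution 1.0, leidenalg 0.10.2). The 25 clusters were named "X-like" from 17 marker lists and 5 lists of epithelial subtypes, fixed before the data were examined. At least 3 markers had to be detected in 25% of a cluster's cells. The limits for mixed clusters were set after the data were seen. Clusters with epithelial and neutrophil markers together (547 cells) were kept apart as mixed. A cluster of 214 cells stayed unnamed because its leading genes held a neutrophil marker, Ly6g, and no epithelial one. By detection in 25% of its cells it had 85% of the epithelial and 27.3% of the neutrophil markers. In batches 1 and 2 the mixed clusters held 3.39% and 0% of cells labelled Ctrl_WT, 2.95% and 2.03% of Ctrl_DSS, 3.07% and 4.91% of TG_WT, and 16.8% and 7.69% of TG_DSS. The unnamed cluster held at most 1.15% of any tag's cells in a batch. No authors' cell annotation was used here.

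Raw counts were summed per class, tag and batch and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test. The settings were TMM scaling, its expression filter, tag and batch as terms, and Benjamini-Hochberg adjustment at 0.05. All adjusted p-values of single genes come from this test unless DESeq2 1.42.0 is named. The batch entered as a block because the labels mark it and all conditions of a batch were processed together. Deviations of sums of the same batch correlated across genes at -0.030 to 0.332 over the 6 pairs of tags. Epithelial-like cells gave 8 sums, 11944 tested genes and 3 residual degrees of freedom. Macrophage and monocyte-like cells gave 6 sums of at least 20 cells, 8992 genes and 1 residual degree of freedom. The other classes had too few cells in some tags and are described by their shares. Levels are in CPM (UMIs scaled to library size), after TMM scaling except for Jup and for Il1b in neutrophil-like cells. Intervals are 95% exact ones that cover counting error only.

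Gene lists were tested with camera (limma 3.58.1, log2 CPM, preset correlation 0.01), beside camera with an estimated correlation and fry. The 25 lists hold 430 genes, 3 of them not among the files' symbols (Mx1, Pla2g2a, Trop2). They cover the inflammasome, p38 MAPK signalling, desmosome, adherens junction, tight junction, keratins, Wnt targets, interferon response, MHC class II, antimicrobial defence, cytokines with chemokines and NF-kB, proliferation, cell death, regeneration with YAP targets, absorptive transport, fatty acid oxidation, goblet mucus, unfolded protein response, oxidative stress, dissociation stress, fibrillar matrix, macrophage activation, neutrophil granules, T cell effectors and hemoglobin. Lists with at least 4 tested members were used, and some genes are in several lists. Named genes are Jup, and per comparison the 10 genes (5 outside epithelial-like cells) with the largest fold change each way. These had to pass the test, change the same way in both batches and average at least 10 CPM. Gene models, ribosomal and mitochondrial genes and immunoglobulin or T cell receptor segments were skipped. Up to 4 members of each list with the smallest p, and the 5 genes with the smallest p where none passed, were also named. Genes of a count of 5 or fewer outside this rule were named after their values were seen.

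The tests were tested on simulated data, with 100 genes changed 2-fold and 100 changed 4-fold in the epithelial-like sums. With dispersions per gene, 12% to 26% of 2-fold and 56% to 75% of 4-fold changes were recovered, and 8.79% to 20% of calls were false. With dispersions from the trend these were 13% to 24%, 70% to 84% and 3.7% to 5.38%. The difference of changes was not simulated. In the macrophage and monocyte-like sums no 2-fold change and at most 21% of 4-fold changes were recovered, and 38.5% to 100% of the calls made with dispersions per gene were false. A simulated list of 20 genes shifted 2-fold in epithelial-like sums had an adjusted p of at most 7.1e-10 with the preset correlation. It lay between 0.046 and 0.114 with an estimated correlation. Genes were drawn independently and list members at random. The simulation therefore cannot tell whether the preset correlation is right for lists whose members vary together.

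Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 test, no expression filter, no replicate block and leaving out each sum. Others were at least 1000 UMIs, at most 10% mitochondrial UMIs, a highest-tag rule, removal of Scrublet calls, equal cell numbers, Leiden resolution 0.5 and the estimated correlation. Chosen after seeing the data were leaving out epithelial-like droplets with leukocyte transcripts, leaving out goblet-like, enteroendocrine-like and tuft-like clusters, and tagged leukocyte-like cells as denominator. Droplets with leukocyte transcripts held any UMI of Ptprc, Csf3r, Cxcr2, Il1r2, Retnlg, Cd3e or Cd79a, or over 0.1% of UMIs from S100a8 and S100a9. Several of these genes are in the neutrophil granule, cytokine or antimicrobial defence lists, so leaving the droplets out lowers such members by selection. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.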

Results

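Transcripts of single cells from mouse colon were counted in 2 batches, each a mix of cells from 4 conditions told apart by hashtag. Batch 1 held 133919905 UMIs and batch 2 held 95408149. After filtering, 7157 cells of batch 1 had a median of 12301 UMIs and 3142 genes, and 6472 cells of batch 2 had a median of 7090.5 UMIs and 2188 genes. A single tag was called on 5511 of these cells, which gave each tag 2 sets of cells, 1 per batch. The tags are named Ctrl_WT, Ctrl_DSS, TG_WT and TG_DSS, and 2 readings of Ctrl_DSS and TG_WT remain open. By name, Ctrl_DSS is wild type given DSS and TG_WT is untreated JUP-KO. By antibody number, Ctrl_DSS is untreated JUP-KO and TG_WT is wild type given DSS. Both readings make Ctrl_WT untreated wild type and TG_DSS JUP-KO given DSS. Groups are called cells labelled with a tag name throughout, since Jup, the targeted gene, was lowest under a tag that reads as wild type by name, which does not settle the reading.

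Jup encodes plakoglobin, a catenin of desmosomes and adherens junctions and the gene targeted in the JUP-KO mice (ENSMUSG00000001552, mm10 chromosome 11, 100368958 to 100397763, minus strand). In epithelial-like cells its level was lowest in cells labelled Ctrl_DSS, at 13.7 CPM in batch 1 (95% upper bound 16.9) and 9.09 in batch 2 (95% upper bound 11.3). Cells labelled Ctrl_WT had 70.9 and 65.6 CPM, and cells labelled TG_WT had 77.9 and 99.2. Cells labelled TG_DSS, JUP-KO in both readings, had 30.4 (23.4 to 38.8) in batch 1 but 68.0 (53.3 to 85.6) in batch 2. Untagged epithelial-like cells had 30.3 and 36.2 CPM. Jup was lower in cells labelled Ctrl_DSS than Ctrl_WT by a log2 fold change of -2.67 (SE 0.385, adjusted p = 0.0445), and -2.40 and -2.84 within the batches. It was higher in cells labelled TG_DSS than Ctrl_DSS (1.97, SE 0.392, adjusted p = 0.0398; 1.07 and 2.77 within the batches). The differences of TG_WT from Ctrl_WT (0.32, SE 0.354, adjusted p = 0.921) and of TG_DSS from TG_WT (-1.02, SE 0.364, adjusted p = 0.404) did not pass. With the tag names taken at their word, the low level was thus in wild type cells given DSS and not in untreated JUP-KO cells. Whether the 3' reads of Jup lie outside the deleted part is not given in the sources used here.

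The direction of both Jup calls was kept under every alternative run. The lower level with Ctrl_DSS than Ctrl_WT had an adjusted p from 7.25e-23 to 0.215 over all of them, the highest without Ctrl_WT in batch 1. It did not pass without a replicate block (0.0819) or without Ctrl_WT in batch 2 (0.0994), Ctrl_DSS in batch 1 (0.0647) or Ctrl_DSS in batch 2 (0.167). The higher Jup level with TG_DSS than Ctrl_DSS ranged from 3.92e-12 to 0.671, and did not pass without the block (0.0732), without Ctrl_WT in batch 1 (0.0597) or 2 (0.062), or without Ctrl_DSS or TG_DSS in batch 2 (0.297 and 0.166).

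**Figure D1:**
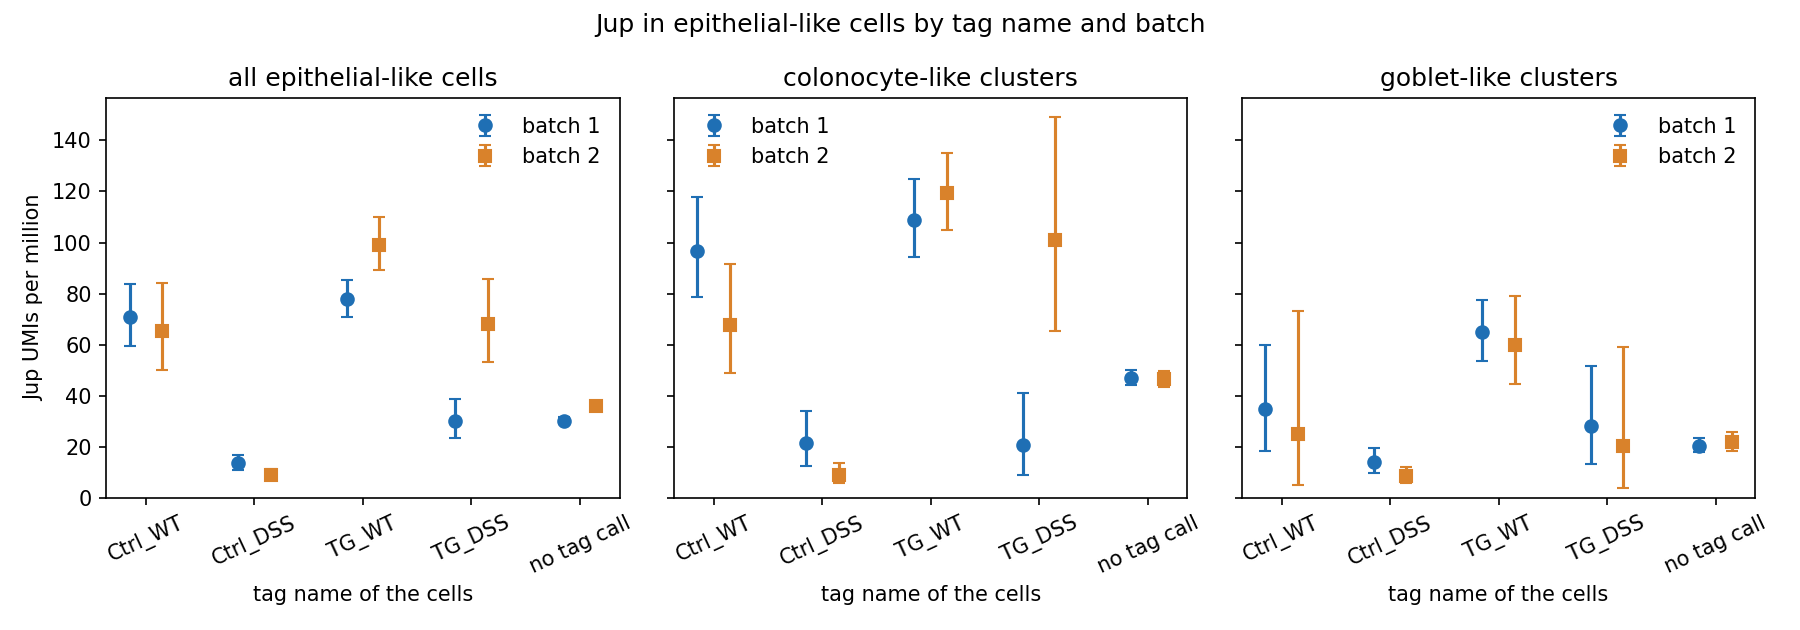
Jup level (CPM) in all epithelial-like, colonocyte-like and goblet-like cells by tag name, 1 marker per batch with its 95% counting interval. In all epithelial-like cells, Ctrl_DSS lies at 13.7 and 9.09 and TG_WT at 77.9 and 99.2.

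Neutrophil-like cells, led by the calprotectin genes S100a9 and S100a8, carried mostly the TG_DSS tag and, in batch 2, also the TG_WT tag. They made up 49.6% (618 of 1245; 95% Clopper-Pearson interval 46.8 to 52.5) and 39.8% (523 of 1314; 37.1 to 42.5) of cells labelled TG_DSS in batches 1 and 2. Among cells labelled TG_WT they were 3.07% (16 of 521) and 22.2% (280 of 1263). Among cells labelled Ctrl_DSS they were 0.491% (2 of 407) and 1.02% (5 of 492). Among cells labelled Ctrl_WT they were 2.82% (5 of 177) and 0 of 92, which allows a share of up to 3.26% (3 counts of 92). Epithelial-like cells were 74.7% ± 5.27 of cells labelled Ctrl_DSS and 6.07% ± 0.84 of cells labelled TG_DSS (mean ± SD of 2 batches), with 57.0% for Ctrl_WT and 39.7% for TG_WT. The epithelial share of TG_WT was 64.7% in batch 1 and 14.8% in batch 2.

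Over leukocyte-like cells alone, neutrophil-like cells were 29.3% ± 1.09 for TG_WT, 55.9% ± 13.5 for TG_DSS, 4.34% ± 3.42 for Ctrl_DSS and 3.33% ± 4.71 for Ctrl_WT (mean ± SD of 2 batches). The small SD of TG_WT does not show precision. Its batches were 16 of 56 cells (95% interval 17.3% to 42.2%) and 280 of 930 cells (27.2% to 33.2%). Within each batch the order was TG_DSS over TG_WT over both other tags. Macrophage and monocyte-like cells were 47.9% of leukocyte-like cells labelled TG_WT, 43.2% of Ctrl_WT, 28.5% of TG_DSS and 24.5% of Ctrl_DSS, with batch values of 57.1% and 38.7%, 29.3% and 57.1%, 26.4% and 30.6%, and 12.5% and 36.5%. T, NK and innate lymphoid-like cells were 32.6% for Ctrl_WT, 31.1% for Ctrl_DSS, 12.1% for TG_WT and 8.60% for TG_DSS, with batch values of 41.3% and 23.8%, 50.0% and 12.2%, 10.7% and 13.5%, and 2.75% and 14.4%. For both classes the order of the tags differed between the batches. An exact two-sided permutation test of 2 batches against 2 cannot go below p = 0.33. No share was tested, and a test over all 8 shares together was not run. Shares are those after dissociation, a viability sort and tagging, and tagging differed by class: 83.4% and 75.7% of epithelial-like cells had no tag, against 15.3% and 2.65% of neutrophil-like cells.

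**Figure D2:**
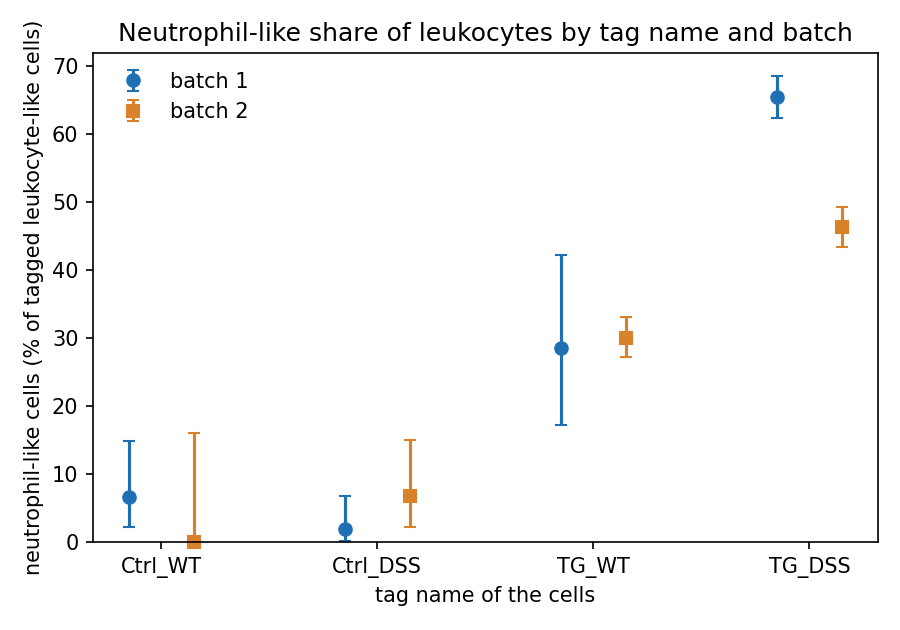
Neutrophil-like cells as a percent of tagged leukocyte-like cells by tag name, 1 marker per batch with its 95% exact binomial interval. TG_DSS is highest in both batches (65.5% and 46.3% of tagged leukocyte-like cells).

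**Figure D3:**
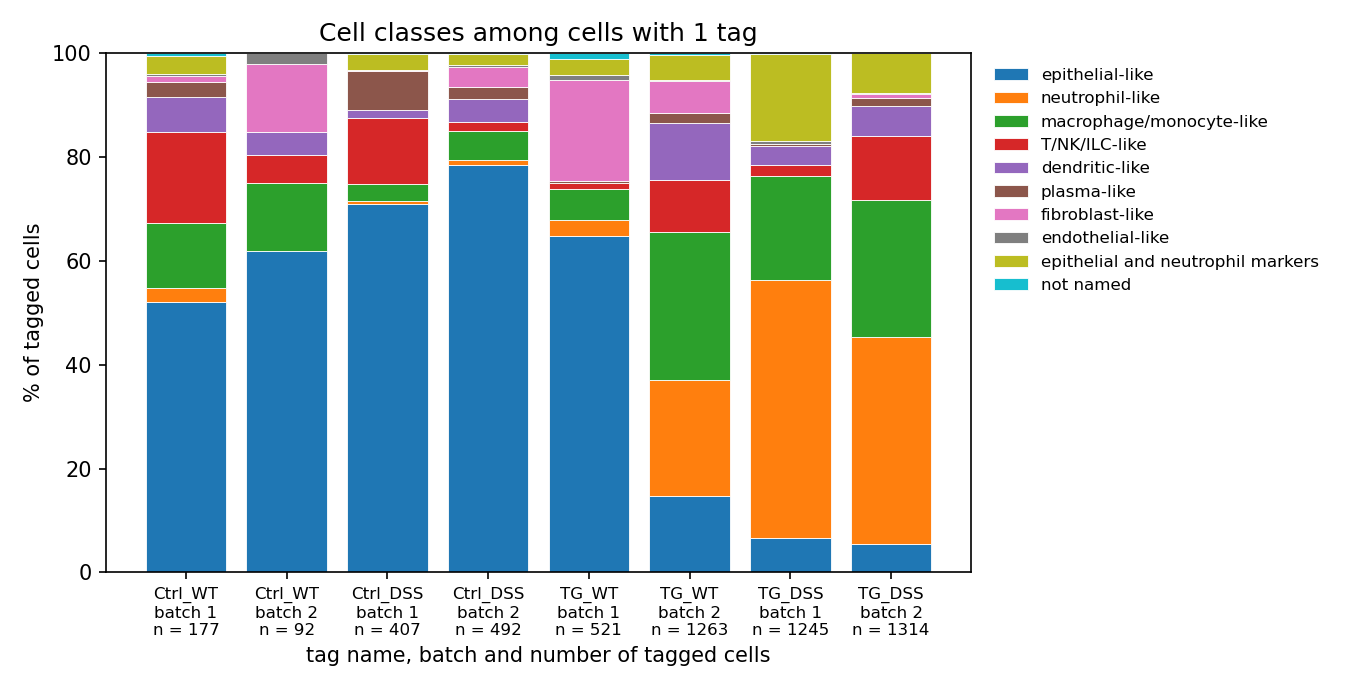
Share of each cell class among tagged cells (percent) for every tag name and batch. Epithelial-like cells range from 78.5% (Ctrl_DSS, batch 2) to 5.48% (TG_DSS, batch 2).

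Cells labelled TG_WT were compared with cells labelled Ctrl_WT, which asks for the effect of JUP-KO without DSS if read by name and of DSS in wild type if read by number. In epithelial-like cells no gene passed edgeR's quasi-likelihood test among 11944, with 663 at an unadjusted p under 0.05 and 34 by DESeq2. The smallest p belonged to Rab3c, a GTPase of secretory vesicles (log2 fold change 3.85, SE 0.442, adjusted p = 0.0812), and to Insl5, an enteroendocrine hormone at 116 and 10.3 CPM with TG_WT and 0.54 and 0 with Ctrl_WT (adjusted p = 0.141). Rgs7 (8.72 and 26.8 CPM against 0 and 2.20), Fry (log2 fold change 1.68) and Prkg2 (-1.28) followed, each at an adjusted p of 0.237. Enteroendocrine-like cells were 0% and 5.26% of epithelial-like cells labelled Ctrl_WT in batches 1 and 2, and 5.34% and 16.6% of those labelled TG_WT.

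By gene list, 15 of 23 passed between TG_WT and Ctrl_WT with the preset correlation, although no member passed over all genes. Cytokines with chemokines and NF-kB (25 members, adjusted p = 7.29e-07), neutrophil granules (11, 5.92e-06) and macrophage activation (11, 1.63e-04) rose, and 0, 0 and 1 members passed adjusted over the list alone. The regeneration list rose (17 members, 3.90e-06, 3 adjusted over the list alone), with Krt7 at 0.81 and Hbegf, a growth factor, at 0.83. So did the inflammasome (20 members, 0.0054), with Il1b at 4.39 (SE 2.04, adjusted p = 0.895), and p38 MAPK signalling (23 members, 0.00515), with the stress sensor Gadd45b at 1.02 (adjusted p = 0.655), each with 0 members adjusted over the list alone. Dissociation stress, the unfolded protein response, goblet mucus, cell death, fibrillar matrix and interferon response rose as well (2.07e-05 to 0.026). Absorptive transport and fatty acid oxidation fell (9.33e-04 each), as did oxidative stress (0.042), although its mean fold change was 0.03 and its median -0.25. None passed with an estimated correlation (smallest adjusted p = 0.325 with an estimated correlation). Leukocyte transcripts moved with the immune lists: after thinning to 2000 UMIs they were in 17.9% of epithelial-like cells labelled TG_WT in batch 2, against 1.79% of Ctrl_WT. In batch 1 they were in 3.75% against 2.22%. Other cells of batch 1 gave no single background: 11.1% of untagged fibroblast-like cells (7 of 63), 3.26% of fibroblast-like cells labelled TG_WT and 1.63% of untagged epithelial-like cells. With droplets with leukocyte transcripts left out, a test chosen after the data were seen, cytokines (0.00193) and the inflammasome (0.0227) still rose with the preset correlation. No list passed in that setting with an estimated correlation (smallest adjusted p = 0.335 with an estimated correlation). There p38 MAPK (0.0528) and macrophage activation (0.15) did not pass, and neutrophil granules and fibrillar matrix had too few tested members. With goblet-like, enteroendocrine-like and tuft-like clusters left out, also chosen after the data were seen, p38 MAPK (0.381), goblet mucus (0.0991), absorptive transport (0.0538), fatty acid oxidation (0.0667), interferon response (0.0722) and oxidative stress (0.653) did not pass.

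The gene count for TG_WT against Ctrl_WT was 2 without Ctrl_WT in batch 1 and 1 without it in batch 2. It was 6 and 5 without Ctrl_DSS, 191 and 12 without TG_WT, and 5 and 2 without TG_DSS, in batches 1 and 2. Without Ctrl_WT in batch 2 the list count was 3.

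Cells labelled Ctrl_DSS were compared with cells labelled Ctrl_WT, which asks for the effect of DSS in wild type by name and of JUP-KO without DSS by number. In epithelial-like cells S100g, a calcium-binding protein of absorptive cells, fell by 3.31 on the log2 scale (SE 0.262, adjusted p = 0.00283; mm10 chromosome X, 162961992 to 162964599), and the sodium-calcium exchanger Slc8a1 fell by 1.93 (SE 0.198, adjusted p = 0.00986). Ceacam10 rose by 2.12 (SE 0.185, adjusted p = 0.00347) and Fabp6, a bile acid-binding protein, by 2.14 (SE 0.348, adjusted p = 0.0435). In all, 22 genes were higher and 51 lower of 11944 by edgeR's quasi-likelihood test.

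Among the other genes higher with Ctrl_DSS than Ctrl_WT were Ccn3 (1.53), the protease Tpsg1 (1.55), Hpd, an enzyme of tyrosine breakdown (1.56), Cd177 (1.83), Ccnb2 (1.76), Pla2g5 (2.12), Hgfac (1.37) and Ramp1 (1.36). Lower were Jup (-2.67), Hdac9 (-2.55), the laminin chain gene Lama3 (-2.17), Sh3kbp1 (-1.73) and 4 more transporter genes: Slc15a1 for peptides (-2.16), Slc30a10 for metal ions (-2.10), Slc51a for bile acids and steroids (-1.83) and Slc40a1 for iron (-1.68). Adjusted p-values of all these lay between 0.0261 and 0.0496, and every one changed the same way in both batches, which the rule for naming them required.

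Of 23 lists, 4 rose and 6 fell with Ctrl_DSS against Ctrl_WT at the preset correlation. Absorptive transport fell (adjusted p = 8.57e-06), with 3 of 21 members past the test over all genes (Slc9a3 -1.37, Slc9a2 -1.28, Slc6a14 -1.08) and 11 adjusted over the list alone. Fatty acid oxidation fell (2.82e-07), with 0 of 16 members over all genes and 8 adjusted over the list alone (Acadvl -0.91, adjusted p = 0.0703). The desmosome list fell (0.00133), with 1 of 11 members, Jup, and 5 adjusted over the list alone; the cytoskeletal linker Dsp was at -0.68 (adjusted p = 0.112) and the cadherin Dsg2 at -0.75 (adjusted p = 0.166). The unfolded protein response rose (2.82e-07; 0 of 14 members, 11 adjusted over the list alone), with Herpud1 at 0.80 (adjusted p = 0.0745). Goblet mucus rose (0.00133; 1 of 14, 8 adjusted over the list alone) with Agr2, an isomerase of mucin folding, at 1.27 (adjusted p = 0.0445). Proliferation (0.00133; 1 of 20, 3 adjusted over the list alone) and dissociation stress (0.00133; 0 of 18) rose, and oxidative stress (0.00699), tight junction (0.0185) and cell death (0.0454) fell. With an estimated correlation none passed (smallest adjusted p = 0.415 with an estimated correlation). By fry, which asks whether members move one way, fatty acid oxidation and the unfolded protein response passed (adjusted p = 0.0469 each). By fry 0 lists passed without a block, without the filter, with at most 10% mitochondrial UMIs, with the highest-tag rule and in both settings chosen after the data were seen. Leaving out Ctrl_WT in batch 1 gave 1 list by fry, and leaving out any other sum gave 0.

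The subtype mix moved with these lists: goblet-like cells were 42.2% and 41.2% of epithelial-like cells labelled Ctrl_DSS and 18.5% and 12.3% of those labelled Ctrl_WT, and colonocyte-like cells 14.5% and 32.4% against 52.2% and 64.9%. With goblet-like, enteroendocrine-like and tuft-like clusters left out, goblet mucus (0.826), oxidative stress (0.375), cell death (0.339) and tight junction (0.147) did not pass, while the other 6 lists kept their direction and passed with the preset correlation. None passed in that setting with an estimated correlation (smallest adjusted p = 0.211 with an estimated correlation). The remaining cells still differed in mix between the tags. Colonocyte-like cells were 42 of 151 and 125 of 211 with Ctrl_DSS in batches 1 and 2, and 48 of 69 and 37 of 46 with Ctrl_WT. Stem and transit-amplifying-like cells were 72 and 54 with Ctrl_DSS, and 12 and 5 with Ctrl_WT. The lists that passed there can therefore not be told apart from subtype mix. Over the alternatives with the preset correlation 2 to 8 lists rose and 3 to 7 fell, and more rose than fell with the highest-tag rule (8 and 4), with equal cell numbers (6 and 4) and without Ctrl_WT (6 and 4) or Ctrl_DSS (6 and 3) in batch 1. The same held without TG_WT in either batch (7 and 6) and without those clusters (4 and 3). The count of 73 genes was 2 without a replicate block and 3 without goblet-like, enteroendocrine-like and tuft-like clusters, a test chosen after the data were seen. It was 5 and 19 without Ctrl_WT, 2 and 3 without Ctrl_DSS, and 315 and 314 without TG_WT, in batches 1 and 2.

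Cells labelled TG_DSS were compared with cells labelled TG_WT, which asks for the effect of DSS in JUP-KO by name and of JUP-KO under DSS by number. S100g alone passed, and fell by 2.51 (SE 0.248, adjusted p = 0.0221; -2.01 and -3.07 within the batches). Next to the threshold were Osm, a cytokine of myeloid cells (4.51, SE 0.556, adjusted p = 0.0526), and Cxcr2, the chemokine receptor of neutrophils (2.63, SE 0.368, adjusted p = 0.0543). At an unadjusted p under 0.05 there were 1270 genes, and DESeq2 called 87. S100g fell in every alternative but was not among the genes that passed without a block, without Scrublet calls, with equal cell numbers or without TG_DSS in batch 2.

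Neutrophil granules (adjusted p = 8.42e-10; 0 of 11 members over all genes, 4 adjusted over the list alone), cytokines with chemokines and NF-kB (1.79e-06; 0 of 25, 11), macrophage activation (4.40e-04; 0 of 11, 2), fibrillar matrix (0.0109; 0 of 4, 3) and p38 MAPK signalling (0.0252; 0 of 23, 6) rose from TG_WT to TG_DSS with the preset correlation. Fatty acid oxidation (0.00193), absorptive transport (0.0043), goblet mucus (0.0043), tight junction (0.0142) and desmosome (0.0144; 0 of 11, 1 adjusted over the list alone) fell, and the first 4 had 0 members adjusted over the list alone. The inflammasome did not pass (0.634). None passed with an estimated correlation (smallest adjusted p = 0.501 with an estimated correlation). Without droplets with leukocyte transcripts, 2 lists passed with the preset correlation, both lower: regeneration and dissociation stress. Neither passed in that setting with an estimated correlation (smallest adjusted p = 0.8415 with an estimated correlation). Of the 10 lists above 8 had enough members there and none passed, and p38 MAPK (mean log2 fold change -0.37) and cytokines (-0.52) turned down while absorptive transport (0.16) and fatty acid oxidation (0.013) turned up.

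The subtype mix moved with the lists that fell from TG_WT to TG_DSS. Colonocyte-like cells were 36.8% and 46.0% of epithelial-like cells labelled TG_WT in batches 1 and 2 and 22.9% and 20.8% of those labelled TG_DSS. Goblet-like cells were 29.7% and 18.2% against 15.7% and 11.1%, and enteroendocrine-like cells 5.34% and 16.6% against 28.9% and 34.7%. With goblet-like, enteroendocrine-like and tuft-like clusters left out, none of the 5 lists that fell passed (0.0649 to 0.899).

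The gene count for TG_DSS against TG_WT was 0 without a replicate block, by edgeR, with 991 genes at an unadjusted p under 0.05. It was 55 and 56 without Ctrl_WT, 31 and 30 without Ctrl_DSS, 122 and 196 without TG_WT, and 19 and 2 without TG_DSS, in batches 1 and 2.

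Cells labelled TG_DSS were compared with cells labelled Ctrl_DSS, which asks for the effect of JUP-KO under DSS by name and of DSS in JUP-KO by number. In epithelial-like cells Spi1, the myeloid transcription factor PU.1, was at 28.8 and 51.7 CPM with TG_DSS and at 0 and 0.11 with Ctrl_DSS (adjusted p = 0.0143). Osm rose by 7.02 (SE 0.664, adjusted p = 0.00196) and Cxcr2 by 6.36 (SE 0.480, adjusted p = 4.63e-04). Ccn3 fell by 2.90 (SE 0.208, adjusted p = 3.92e-04) and the kallikrein Klk1 by 1.83 (SE 0.202, adjusted p = 0.00347). In all, 394 genes were higher and 93 lower of 11944 by edgeR's quasi-likelihood test.

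Leukocyte transcripts moved with these genes. Thinned to 2000 UMIs, 42.5% and 49.3% of epithelial-like cells labelled TG_DSS had leukocyte RNA in batches 1 and 2, against 2.43% and 1.62% of those labelled Ctrl_DSS and 1.63% and 2.85% of untagged ones. Unthinned these were 53.0% and 55.6%, 9.34% and 15.3%, and 8.23% and 11.3%. Thinning left out 3 and 5 cells of TG_DSS, 1 and 16 of Ctrl_DSS and 278 and 154 untagged cells. Untagged fibroblast-like cells, which should lack these transcripts, had them in 11.1% and 5.12% after thinning. Median UMIs were 19685 and 10833.5 with TG_DSS, 21350 and 20427 with Ctrl_DSS, 15620 and 13304.5 in untagged epithelial-like and 5645 and 5442.5 in untagged fibroblast-like cells. Without these droplets, a test chosen after the data were seen, 22 genes passed (8 higher, 14 lower), 16 of them among the 487. This left 39 and 32 of the 83 and 72 cells labelled TG_DSS, so lost power was not told apart from lost leukocyte RNA.

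Other genes higher with TG_DSS than Ctrl_DSS included Tnfaip2 (7.59), the chemokine Cxcl3 (6.79), Ankrd33b (6.85) and Piezo2 (6.70), and Mcemp1 at 22.4 and 52.6 CPM against 0.15 and 0. Lower were Rbp4 (-2.48), Tpsg1 (-2.21), Fkbp11 (-2.05), Nupr1 (-2.00), Fabp6 (-1.92), Ramp1 (-1.90), Clps (-1.90) and Copz2 (-1.85). Their adjusted p-values lay between 0.00219 and 0.0414.

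At the preset correlation 7 lists rose and 3 fell from Ctrl_DSS to TG_DSS, and with an estimated correlation none passed (smallest adjusted p = 0.52 with an estimated correlation). Neutrophil granules rose (1.39e-11; 3 of 11 members over all genes, all 11 adjusted over the list alone), as did cytokines with chemokines and NF-kB (4.19e-11; 9 of 25, 18 adjusted over the list alone), with Nfkbiz, an NF-kB regulator, at 2.06 (adjusted p = 0.00416), and macrophage activation (2.25e-05; 2 of 11, 6). The p38 MAPK list rose (0.00317; 5 of 23, 7 adjusted over the list alone) with Gadd45b at 1.84 (adjusted p = 0.0069), the RNA-decay factor Zfp36 at 1.15 (0.00906), the phosphatase Dusp16 at 1.73 (0.0102) and the p38 substrate kinase Mapkapk2 at 1.30 (0.0207). The p38 kinase gene Mapk14 was at 0.34 (adjusted p = 0.458). Without droplets with leukocyte transcripts Gadd45b was at -0.62 and Mapkapk2 at -0.66. The inflammasome list rose (0.0434) with 0 of 20 members over all genes and 2 adjusted over the list alone. Among its members, Il1b was at 1548 and 1885 CPM with TG_DSS against 6.80 and 6.54 (adjusted p = 0.16), Nlrp3 at 121 and 248 against 1.36 and 0.57 (adjusted p = 0.156), and Casp1 at -0.19 (SE 0.206, adjusted p = 0.687). Fibrillar matrix (0.00381; 1 of 4, 3) and cell death (0.00904; 2 of 20, 7) rose too.

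The unfolded protein response fell from Ctrl_DSS to TG_DSS (adjusted p = 2.71e-04; 2 of 14 members, 6 adjusted over the list alone; Pdia6 -0.95), as did goblet mucus (0.0062; 3 of 14, 4; Muc2, the main intestinal mucin, -1.61, adjusted p = 0.0217) and proliferation (0.00996; 0 of 20, 0). With goblet-like, enteroendocrine-like and tuft-like clusters left out, 10 lists rose and 1, proliferation (0.0142), fell with the preset correlation. None passed in that setting with an estimated correlation (smallest adjusted p = 0.265 with an estimated correlation). There the unfolded protein response (0.714) and goblet mucus (0.0802, direction up) did not pass and Muc2 was at 1.69, so a fall of these within the remaining cells is not shown. The other 13 lists did not pass (0.0579 to 0.927): antimicrobial defence, dissociation stress, keratins, adherens junction, regeneration, desmosome, oxidative stress, Wnt targets, tight junction, fatty acid oxidation, interferon response, MHC class II and absorptive transport.

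Without droplets with leukocyte transcripts, the p38 MAPK (adjusted p = 0.193, direction turned down, mean log2 fold change -0.30), cytokine (0.116) and macrophage activation (0.854) lists did not pass for TG_DSS against Ctrl_DSS, and neutrophil granules and fibrillar matrix had too few tested members. The genes that picked the droplets include members of the neutrophil granule and cytokine lists, whose loss was thus partly fixed in advance. In that setting the inflammasome (0.00647) and cell death (0.00229) rose and the unfolded protein response (5.99e-04), goblet mucus (0.0469) and proliferation (0.00875) fell, as they had with all droplets. Fatty acid oxidation (5.99e-04), absorptive transport (7.96e-04), tight junction (0.00229), adherens junction (0.0109) and antimicrobial defence (0.0469) rose, and dissociation stress fell (7.97e-04). None of these passed with an estimated correlation.

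Goblet-like cells were 15.7% and 11.1% of epithelial-like cells labelled TG_DSS and enteroendocrine-like cells 28.9% and 34.7%, against 2.77% and 1.81% for the latter with Ctrl_DSS. The count of 487 was 26 without a replicate block, all 26 among the 487, and 157 without Scrublet calls. The count was 13 (5 shared) without goblet-like, enteroendocrine-like and tuft-like clusters, which left 42 and 31 cells labelled TG_DSS. It was 247 and 13 without Ctrl_DSS, 925 and 870 without TG_WT, and 284 and 105 without TG_DSS, in batches 1 and 2.

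**Figure D4:**
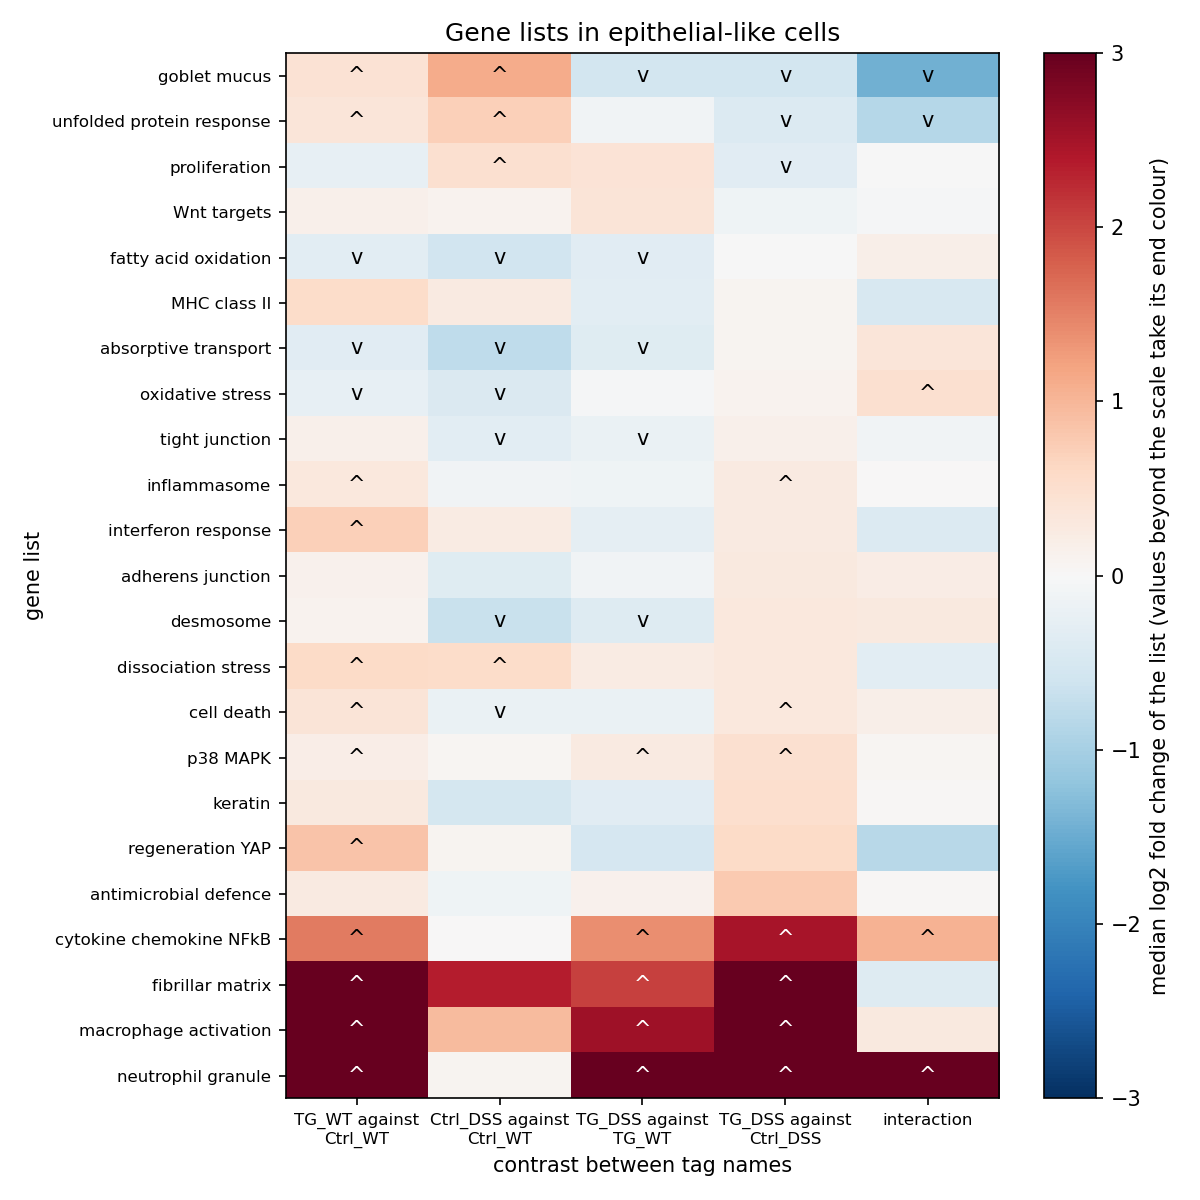
Median log2 fold change of each gene list in epithelial-like cells for the 5 comparisons; upward and downward marks show lists at an adjusted p under 0.05 with the preset correlation. From Ctrl_DSS to TG_DSS, 7 lists rose and 3 fell, and none passed with an estimated correlation.

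The change from TG_WT to TG_DSS was compared with the change from Ctrl_WT to Ctrl_DSS, a difference that is the same in both readings. It passed for 4 genes: Ccn3 (-2.93, SE 0.280, adjusted p = 0.0156), Tpsg1 (-2.73, SE 0.312, adjusted p = 0.0213), Hpd (-2.53, SE 0.293, adjusted p = 0.0213) and Slc8a1 (2.42, SE 0.275, adjusted p = 0.0213). Ccn3 was at 134 and 153 CPM with Ctrl_WT, 385 and 443 with Ctrl_DSS, 165 and 128 with TG_WT, and 53.4 and 57.9 with TG_DSS. Slc8a1 was at 247 and 262, 62.7 and 71.1, 136 and 118, and 151 and 212 CPM. Tpsg1 lies on mm10 chromosome 17, 25369273 to 25374442, Slc8a1 on chromosome 17, 81373105 to 81738377, and Hpd on chromosome 5, 123171807 to 123182727.

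In this difference of changes the unfolded protein response (2.79e-07; 0 of 14 members, 7 adjusted over the list alone) and goblet mucus (7.38e-06; 0 of 14, 4; Agr2 -1.84, adjusted p = 0.0865) were lower. Neutrophil granules (2.79e-07; 0 of 11, 0), cytokines with chemokines and NF-kB (2.85e-04; 0 of 25, 2) and oxidative stress (0.0438; 0 of 16, 0) were higher. With droplets with leukocyte transcripts left out, cytokines (0.683, direction down) and oxidative stress (0.0993) did not pass, and neutrophil granules had too few tested members. In that setting the unfolded protein response (1.44e-06) and goblet mucus (2.99e-04) stayed lower, dissociation stress (1.33e-06) and regeneration (0.0161) were lower too, and absorptive transport (1.11e-05) and fatty acid oxidation (1.46e-05) were higher. None of these passed there with an estimated correlation (smallest adjusted p = 0.361 with an estimated correlation). With goblet-like, enteroendocrine-like and tuft-like clusters left out, the unfolded protein response stayed lower (0.023) and goblet mucus did not pass (0.869, direction up). None passed in that setting with an estimated correlation (smallest adjusted p = 0.555 with an estimated correlation). With all droplets none passed with an estimated correlation either (smallest adjusted p = 0.835 with an estimated correlation). The gene count was 0 by edgeR without goblet-like, enteroendocrine-like and tuft-like clusters, with 453 at an unadjusted p under 0.05, and of the 4 genes Slc8a1 alone was tested there (1.76, not passing). It was 5 without Ctrl_WT in batch 1, with 1 of the 4 among them, 13 without Ctrl_WT in batch 2, 0 without Ctrl_DSS in batch 1 or 2 (898 and 542 unadjusted), 53 and 165 without TG_WT in batches 1 and 2, 6 without TG_DSS in batch 1 (3 of the 4 among them) and 0 without TG_DSS in batch 2 (910 unadjusted). DESeq2 called 73.

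Some lists that did not pass in epithelial-like cells had a test direction that differed in sign from their mean or median fold change. These were the inflammasome and neutrophil granules for Ctrl_DSS against Ctrl_WT, the inflammasome and oxidative stress for TG_DSS against TG_WT, and Wnt targets, fatty acid oxidation, MHC class II and absorptive transport for TG_DSS against Ctrl_DSS. In the difference of changes they were fibrillar matrix, adherens junction, Wnt targets and tight junction.

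In macrophage and monocyte-like cells, Cd163, a hemoglobin scavenger receptor of resident macrophages, was lower with TG_WT than Ctrl_WT (-5.95, SE 0.985, adjusted p = 0.0274) and higher with TG_DSS than TG_WT (3.84, SE 0.669, adjusted p = 0.0225). Its level was 87.1 CPM with Ctrl_WT, 70.3 with Ctrl_DSS, 0 and 8.71 with TG_WT and 20.8 and 117 with TG_DSS. Cd163 is a leading gene of a cluster of 49 cells joined in this class with a cluster of 1054, and a different mix of these clusters was not told apart from a change in level. With TG_WT, Ear2 (-5.92, adjusted p = 0.0173), Fbxo32 (-4.97, adjusted p = 0.0178) and Cd209f (0 CPM in both batches against 61.0, adjusted p = 0.0433) were lower as well. From TG_WT to TG_DSS, Xcl1 (-6.39, adjusted p = 0.00334), Ifnb1 (50.7 and 35.3 CPM against 0.69 and 0, adjusted p = 0.00391) and Olfr111 (92.2 and 12.6 CPM against 2.08 and 0.50, adjusted p = 0.00993) were among 5 genes that fell and 2 that rose. Xcl1 is a leading gene of the T, NK and innate lymphoid-like cluster and Fbxo32 of a colonocyte-like cluster, so RNA or cells of other classes could underlie these differences. Gdf3 alone passed between TG_DSS and Ctrl_DSS (-5.64, adjusted p = 0.0162). No gene passed by edgeR between Ctrl_DSS and Ctrl_WT (396 at an unadjusted p under 0.05) or in the difference of changes (387), and DESeq2 called 0 in both.

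Between Ctrl_DSS and Ctrl_WT each side was 1 sum, from different batches, and 0% of simulated 4-fold changes were recovered. The absence of calls there therefore says little. The calls of Cd163, Ear2, Fbxo32, Cd209f and Gdf3 against Ctrl_WT or Ctrl_DSS rest on 1 sum of 22 and 1 of 27 cells, assumed to vary like the other groups, with 1 residual degree of freedom. Without a block, with DESeq2 size factors or with at most 10% mitochondrial UMIs edgeR called 0 genes in both comparisons (384 to 679 at an unadjusted p under 0.05), while DESeq2 called 0 against Ctrl_WT and 8 against Ctrl_DSS. The count for TG_WT against Ctrl_WT was 0 without the Ctrl_DSS sum (447 unadjusted), and that for TG_DSS against Ctrl_DSS was 0 without the Ctrl_WT sum (679) and 10 with the highest-tag rule.

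The 7 genes between TG_WT and TG_DSS did not hold under several alternatives either. By edgeR 0 passed without a block (80 at an unadjusted p under 0.05), with at most 10% mitochondrial UMIs (87) and without the Ctrl_DSS sum (113), and by DESeq2 0 passed (29). Without the Ctrl_WT sum 2 passed, both lower, and with DESeq2 size factors 5, all lower. With the highest-tag rule 16 passed, among them all 7.

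Lists passing in macrophage and monocyte-like cells with the preset correlation numbered 6, 4, 9, 13 and 7 over the 5 comparisons, and none passed with an estimated correlation (smallest adjusted p = 0.757 with an estimated correlation, for TG_DSS against Ctrl_DSS). In that comparison T cell effectors (0.0389; 6 members) and hemoglobin (0.0155; 4 members) were higher, and MHC class II was lower (0.00375; 0 of 7 members, 1 adjusted over the list alone). Absorptive transport, a list of epithelial genes, was higher there too (2.04e-07; 0 of 18 members, 7 adjusted over the list alone). Ctrl_WT in batch 2 and Ctrl_DSS in batch 1 had under 20 cells and were left out.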

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

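The tests of tag background and of unstained Ctrl_DSS leukocytes, and the settings without droplets with leukocyte transcripts or without secretory and tuft-like clusters, were chosen after the results were seen.

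In epithelial-like cells, 4 genes differed in their change from TG_WT to TG_DSS against that from Ctrl_WT to Ctrl_DSS, by a test of the difference itself. Slc8a1 was at 2.42, Ccn3 at -2.93, Tpsg1 at -2.73 and Hpd at -2.53 on the log2 scale. By the preset correlation 5 lists differed as well, and 0 with an estimated correlation. Goblet-like cells were 42.2% and 41.2% of epithelial-like cells labelled Ctrl_DSS and 15.7% and 11.1% of those labelled TG_DSS, and Ccn3 is a leading gene of a goblet-like cluster. Without goblet-like, enteroendocrine-like and tuft-like clusters 0 genes passed by edgeR (453 at an unadjusted p under 0.05), and of the 4 only Slc8a1 had enough counts to be tested (1.76, not passing). With droplets with leukocyte transcripts left out, all 4 passed in the same direction.

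Several groups of cells entered no comparison. No tag was called on 4541 cells in batch 1 and 2612 in batch 2, and 83.4% and 75.7% of epithelial-like cells were among these. The mixed clusters held 547 cells with epithelial and neutrophil markers together. The unnamed cluster held 214 cells, of which 93.5% and 91.5% had no tag.

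Jup was lowest in cells labelled Ctrl_DSS, wild type given DSS by name. A different mix of epithelial subtypes and tags at background level are argued against: within goblet-like and colonocyte-like cells the ratio of Ctrl_DSS to Ctrl_WT and TG_WT together was at most 0.238 (lowest 0.086), and the ratio to untagged epithelial-like cells was at most 0.453 (95% upper bound 0.559). An exchange of the names Ctrl_DSS and TG_WT between conditions remains open, and it could explain the low level. The prediction written beforehand was antimicrobial defence higher with TG_WT than Ctrl_DSS at a camera p under 0.05. It was met with the preset correlation (camera p = 0.00735), but not with an estimated correlation (camera p = 0.26), with which no list passed in any comparison. The estimated correlation and a low Jup ratio of TG_DSS to TG_WT were required in addition to that prediction. The antimicrobial defence list holds the neutrophil genes S100a8 and S100a9. Leukocyte RNA, thinned to 2000 UMIs, was in 3.75% and 17.9% of epithelial-like cells labelled TG_WT against 2.43% and 1.62% of Ctrl_DSS. Colonocyte-like cells were 36.8% and 46.0% against 14.5% and 32.4%. The list result therefore cannot tell an exchange from leukocyte RNA or subtype mix. TG_DSS, JUP-KO in both readings, had 30.4 CPM against 77.9 of TG_WT in batch 1 and 68.0 against 99.2 in batch 2 (a ratio of 0.686), in droplets that may also hold tagged leukocytes. For the low level itself, the exchange cannot be told apart from an effect of DSS on Jup in wild type. That effect stays open as untested. It would not bear on Jup with TG_WT, untreated JUP-KO by name, which was not lower than with Ctrl_WT. Nor would it bear on the neutrophil-like cells labelled TG_WT. Whether JUP-KO lowers the counted Jup reads is not given in the sources used here.

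Nearly all tagged neutrophil-like cells carried the TG_DSS or TG_WT tag, although TG_WT is untreated by name. Leukocytes of the Ctrl_DSS condition might have gone unstained. This could hold for a part of them only, since 104 and 74 leukocyte-like cells carried that tag in batches 1 and 2. An upper limit for the neutrophil-like share of Ctrl_DSS leukocytes adds every untagged neutrophil-like cell (116 and 22) to that tag. This limit was 28.1% in batch 2, below the 30.1% of TG_WT. In batch 1 it was 53.6%, above the 28.6% of TG_WT, so the batches leave this open for neutrophil-like cells. With names exchanged, TG_WT would hold DSS-treated wild type cells and more recruited monocytes. The log2 ratio of Ly6c2, a monocyte gene, to C1qa, a macrophage gene, was higher with TG_WT than Ctrl_DSS by 5.17 in batch 2, but batch 1 had 0 Ly6c2 UMIs in both, so the exchange cannot be told apart from a genotype effect, which was not tested.

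Epithelial-like cells with the TG_DSS tag may be droplets that hold an epithelial cell and a tagged leukocyte. The share with leukocyte RNA, thinned to 2000 UMIs, was 17.3 times that of untagged epithelial-like cells in the lower batch and 26.1 times in the higher (unthinned, 4.94 in the lower). The values this explanation needs are thus present. It would place the genotype and treatment of those epithelial cells in doubt, Jup included. Leukocyte RNA taken up or made by injured epithelium of that condition stays open as an untested biological explanation.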

How the results depend on the processing

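The settings without droplets with leukocyte transcripts, without goblet-like, enteroendocrine-like and tuft-like clusters (below, without secretory clusters) and with tagged leukocyte-like cells as denominator were chosen after seeing the data. Of 497 summary values under alternatives 326 stayed within the limits set for them and 171 did not. Counts had to stay within 1.5-fold, and a mean share within the SD of its 2 batches. Jup was judged like the named genes. Leaving out either batch of a tag always keeps its share within that SD, so those values could not fail. Of 1513 values of named genes that had passed, 939 kept direction and side of the threshold, 562 no longer passed and 12 reversed. Another 27 values newly passed. A change of sign counted as reversed where either value passed. The cause was not tested unless given.

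Counts of changed genes in epithelial-like cells are given in the order TG_WT against Ctrl_WT, Ctrl_DSS against Ctrl_WT, TG_DSS against TG_WT, TG_DSS against Ctrl_DSS and the difference of changes (0, 73, 1, 487 and 4). Without the filter on low counts they were 158, 659, 477, 1361 and 350. By DESeq2 they were 34, 281, 87 and 73, with the fourth within limits at 683. With the highest-tag rule they were 27, 173, 182, 815 and 118. Without a replicate block the middle 3 were 2, 0 and 26, and in edgeR the 0 had 991 genes at an unadjusted p under 0.05. With at most 10% mitochondrial UMIs they were 11 for Ctrl_DSS against Ctrl_WT, 7 for TG_DSS against TG_WT and 0 for the difference of changes (883 unadjusted). Without Scrublet calls the last 3 were 0 (816 unadjusted), 157 and 2. With equal cell numbers they were 2 for TG_WT against Ctrl_WT, 95 for TG_DSS against TG_WT and 21 for the difference of changes. Without droplets with leukocyte transcripts they were 3, 5, 22 and 15, the second staying within limits at 77. Without secretory clusters the last 4 were 3, 3, 13 and 0 (453 unadjusted). Leaving out 1 sum gave 1 to 191, 2 to 315, 2 to 196, 13 to 925 and 0 to 165. A group left with 1 sum was assumed to vary like the others.

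Lists passing in epithelial-like cells were 15, 10, 10, 10 and 5 in that order, and 0 in each with an estimated correlation. For TG_DSS against TG_WT the count was 2 without droplets with leukocyte transcripts, 6 without secretory clusters and 6 without Scrublet calls. For the difference of changes it was 9 with the highest-tag rule, 8 without the filter, 9 without secretory clusters and 8 without Scrublet calls. Leaving out 1 sum gave 3 to 17 lists for TG_WT against Ctrl_WT and 6 to 11 for the difference of changes.

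The lower Jup level with Ctrl_DSS than Ctrl_WT kept its direction and no longer passed without a replicate block (-2.66), with the highest-tag rule (-2.41), without Scrublet calls (-2.96), without droplets with leukocyte transcripts (-2.72) and without secretory clusters (-2.84), and lay between -3.24 and -2.18 leaving out 1 sum. The higher Jup level with TG_DSS than Ctrl_DSS likewise no longer passed without a block (2.02), with the highest-tag rule (1.91), without Scrublet calls (2.12), with equal cell numbers (1.45), without droplets with leukocyte transcripts (2.33) and without secretory clusters (2.25), and lay between 1.32 and 2.52 leaving out 1 sum. Without the filter Jup newly passed for TG_DSS against TG_WT (-1.07) and for the difference of changes (1.56).

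Without secretory clusters Hgfac reversed for Ctrl_DSS against Ctrl_WT (-0.0249), and for TG_DSS against Ctrl_DSS Fkbp11 (0.0404), Ramp1 (0.45), Muc2 (1.69) and Dusp1 (-0.0351). Without droplets with leukocyte transcripts Gadd45b (-0.62), Mapkapk2 (-0.66), Junb (-0.0435), Socs3 (-0.11), Dusp1 (-1.53) and Thbs1 (-0.40) reversed for TG_DSS against Ctrl_DSS. In macrophage and monocyte-like cells Hba-a1 reversed for TG_DSS against TG_WT without Scrublet calls (2.42).

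In macrophage and monocyte-like cells TG_WT against Ctrl_WT (4 genes) gave 7 without the filter. It gave 0 by DESeq2 (77 unadjusted) and in edgeR 0 with DESeq2 size factors (434), without a block (509), with at most 10% mitochondrial UMIs (384), with equal cell numbers (100) and without the Ctrl_DSS sum (447). TG_DSS against TG_WT (7 genes) gave 23 without the filter, 16 with the highest-tag rule, 13 without Scrublet calls, 2 without the Ctrl_WT sum, 1 with equal cell numbers, 0 by DESeq2 (29 unadjusted), and in edgeR 0 without a block (80), with at most 10% mitochondrial UMIs (87) and without the Ctrl_DSS sum (113). TG_DSS against Ctrl_DSS (1 gene) gave 8 by DESeq2, 69 without the filter, 10 with the highest-tag rule and 5 without Scrublet calls. It gave 0 in edgeR with DESeq2 size factors (679 unadjusted), without a block (617), with at least 1000 UMIs (668), with at most 10% mitochondrial UMIs (595), with equal cell numbers (231) and without the Ctrl_WT sum (679). The difference of changes (0 genes in edgeR, 387 unadjusted, 0 by DESeq2) gave 5 without the filter. Lists passing were 0 with an estimated correlation in all 5. Without Scrublet calls they were 3 for TG_WT against Ctrl_WT, 1 for Ctrl_DSS against Ctrl_WT, 8 for TG_DSS against Ctrl_DSS and 3 for the difference of changes. With equal cell numbers they were 3 for TG_DSS against TG_WT, 8 for TG_DSS against Ctrl_DSS and 4 for the difference of changes. Without a block they were 0 for Ctrl_DSS against Ctrl_WT and for the difference of changes.

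Mean shares of epithelial-like cells moved with at most 10% mitochondrial UMIs to 48.5% for Ctrl_WT and 5.11% for TG_DSS. With the highest-tag rule they were 36.6% for Ctrl_WT, 52.4% for Ctrl_DSS and 4.58% for TG_DSS. For TG_DSS they were 5.01% without Scrublet calls and 8.66% at resolution 0.5. Macrophage and monocyte-like cells labelled Ctrl_WT were 15.5% with at most 10% mitochondrial UMIs, 17.4% with the highest-tag rule and 13.6% at resolution 0.5, and those labelled Ctrl_DSS 9.29% with the highest-tag rule. With that rule neutrophil-like cells were 1.34% of Ctrl_DSS, and T, NK and innate lymphoid-like cells 21.2% of Ctrl_WT and 15.9% of Ctrl_DSS. Over leukocyte-like cells, whose smaller denominator raises every share, neutrophil-like cells were 4.34% for Ctrl_DSS, 29.3% for TG_WT and 55.9% for TG_DSS. Macrophage and monocyte-like cells were 43.2% for Ctrl_WT, 24.5% for Ctrl_DSS, 47.9% for TG_WT and 28.5% for TG_DSS, and T, NK and innate lymphoid-like cells 32.6%, 31.1% and 12.1% for the first 3.

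In macrophage and monocyte-like cells, leaving out a TG_WT or TG_DSS sum left no residual degrees of freedom and gave no value. Leaving out the only sum of Ctrl_WT or Ctrl_DSS left 3 tags, on which the comparisons that do not need the missing tag were tested. With the highest-tag rule both Ctrl_WT sums were under 20 cells, and the comparisons with Ctrl_WT gave no value. At resolution 0.5 neutrophil-like cells merged into a mixed cluster and gave no value. The highest-tag rule left Ctrl_WT in batch 1 under 20 epithelial-like cells, and that sum was dropped. Macrophage and monocyte-like sums of 12 cells (Ctrl_WT, batch 2) and 13 cells (Ctrl_DSS, batch 1) were too small to be used.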

Other observations

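Untagged epithelial-like cells had Jup at 30.3 and 36.2 CPM in batches 1 and 2. In them, colonocyte-like cells were 36.8% and 55.2%, goblet-like cells 13.3% and 16.3% and enteroendocrine-like cells 4.70% and 4.44%.

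Neutrophil-like cells had Il1b, an inflammasome substrate, at 27330 and 21277 CPM with TG_DSS (618 and 523 cells) and at 29513 and 15243 CPM with TG_WT (16 and 280 cells). Untagged neutrophil-like cells had Il1b at 24877 and 18764 CPM (116 and 22 cells).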
